A study of Mus musculus with 12 samples.

How the data were processed

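RNA from mouse embryonic fibroblasts of 2 genotypes, wild type and Ulk1/2 double knockout, each untreated or treated with IFNβ at 2500 IU/ml for 6 h, was measured on 12 arrays, 3 in each of the 4 groups. Per the labels, biotin-labelled cRNA was hybridised to an Illumina mouse bead array. The deposited intensity values are 1 linear summary per probe and array, with no background subtracted and no normalization. The deposited detection p-value of each probe and array is the share of negative control probes at least as bright, in steps of 1 in 936. A second deposited table holds log2 values that have the same quantiles on every array, with a median of 6.53, and that follow log2 of the intensity closely, so the authors normalized by quantiles without background subtraction; the software is not given in the sources used here. Values computed here started from the intensities and detection p-values, and the authors' log2 table served as an alternative.

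Of 45281 probes, 34885 were annotated to 1 gene, 18 to several and 10378 to none; the last 2 kinds were left out of the gene tests. Entrez identifiers of 34807 probes were matched to the reference gene table, which changed 0 symbols, and 19057 genes were named. No reference genome was used here, so probe sequences were not placed. Background was corrected with the normexp model fitted from the detection p-values, with an offset of 16, followed by quantile normalization and log2 (neqc of limma 3.58.1, in R 4.3.3, with version 1.17.8 of data.table). Probes with a detection p under 0.01 on at least 3 arrays were kept, 15856 in all, of which 13737 were named, and each gene was represented by its probe with the highest mean, which left 8898 genes. A dim group can hold a signal that is not measured. Where a gene was not detected on any array of the dimmer group, the fold is given as a lower bound, from the brighter group's mean against the higher of the lowest detected signal on each dim array and the probe's own signal there.

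A single limma model of 4 group means was fitted over the 12 arrays, with 8 residual degrees of freedom and 5.56 prior degrees of freedom, and moderated with eBayes. It gave 5 contrasts: IFNβ against untreated in each genotype, the difference of these changes (the interaction, DKO minus WT), and DKO against WT untreated and after IFNβ. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and counts are also given at a fold change of at least 2. Gene lists, 32 with 994 entries of which 912 were on the array, were tested with camera at a preset correlation of 0.01 where they held at least 5 tested genes, adjusted over lists and contrasts. The mean over the antiviral list was compared by a 2-sided exact permutation test. It exchanges the genotypes of the treated arrays' rises over the untreated mean of their own genotype, and leaves out the spread of the untreated arrays. The contrasts, lists, filters and most alternatives were fixed before the data were examined. So was the rule for genes named in the text. It took, in each contrast, the 8 largest rises and falls that were detected in each group, the 4 rises and falls with the largest bounds (not in the interaction), Ulk1 and Ulk2, and from each list up to 4 called members with the largest change, or up to 2 with the smallest p where none passed; predicted and unnamed transcripts were skipped. Genes named outside this rule are said to be so. For 108 named genes with another probe on the array, 282 comparisons of that probe with the one used gave 140 like results, 91 where it did not pass, 23 where its change was under 50% as large, 1 opposite call and 27 where the probe used had not passed itself.

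The lists covered antiviral interferon-stimulated genes, interferon pathway components, MHC class I and the immunoproteasome, interferon-inducible GTPases, chemokines and cytokines, NF-kB targets, p38 MAPK and AP-1, autophagy, lysosome, NRF2 targets, ER stress and ATF4 targets, cholesterol synthesis, glycolysis and hypoxia, cell cycle, p53 targets, extracellular matrix, heat shock, ribosomal proteins, oxidative phosphorylation, Hox, imprinted and sex-linked genes, and markers of fibroblasts, smooth muscle, skeletal muscle, adipocytes, cartilage and bone, epithelia, endothelia, leukocytes, neural cells and pluripotent cells.

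Arrays were checked for pairs and batches. Correlations between arrays across probes are across genes, which are not independent replicates. After group means were taken out, arrays of different background sets correlated at -0.62 to -0.13. Within a set and genotype, same-numbered arrays correlated at 0.34 to 0.64 and others at 0.06 to 0.25. Within a set but across genotypes, same-numbered arrays correlated at 0.34 to 0.45 and others at 0.31 to 0.43, so the number adds little there. The numbers were therefore read as pairing arrays within a genotype only, and a block of this kind was an alternative. The test was also run on simulated data built from the residual spread, with 200 changed genes among 8898 in 5 runs. For IFNβ in WT it recovered 48.4%, 89.3% and 99.7% of changes of 0.5, 1 and 2 log2, with 5.28% false calls, and for the interaction 10.4%, 66.0% and 97.6%, with 4.93%. The simulated values vary independently between arrays and genes. The real arrays correlate as given above, so these rates need not hold for them.

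The alternatives were no background correction, median scaling, cyclic loess, the authors' log2 values, an offset of 50, other detection filters or none, every probe or the mean of a gene's probes, the arrays of a contrast alone, a trended robust prior, replicate blocks, each array left out, an adjusted p under 0.01, and for lists an estimated correlation, fry and lists without antiviral members. A block of the background sets, each set alone, a replicate block within genotype and subsets of the antiviral list were added after the data were seen. So were splits of the arrays with the genotype effect, or this and the background set, of an additive model taken out.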

Results

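Gene expression was measured on 12 Illumina mouse whole-genome bead arrays in mouse embryonic fibroblasts, connective tissue cells grown from embryos. The cells either carried both Ulk1 and Ulk2 (wild type, WT) or lacked both (double knockout, DKO). Ulk1 and Ulk2 encode related serine/threonine kinases known for starting autophagy, the recycling of cell contents through lysosomes. Each genotype was left untreated or given interferon beta (IFNβ), a type I interferon that cells release on viral infection, at 2500 IU/ml for 6 h. The 4 groups held 3 arrays each, and that number limits the precision of every value given here. The labels do not state that the replicates were separate cultures, so each p-value measures only the spread between these samples. The question put by the study title is the part that ULK1 plays in type I interferon signalling. Between 13732 and 15240 of 45281 probes were detected per array, which is 30.3% to 33.7%. Median intensity fell into 2 separate sets of 6 arrays, from 86.5 to 87.9 and from 97.5 to 99.7 intensity units. Each set held arrays of all 4 groups, but unevenly. The lower set held 2 arrays of each WT group and 1 of each DKO group, and the higher set 1 and 2. Of the variance between arrays, the leading principal component took 49.5% and parted the genotypes, the next took 32.6% and parted treated from untreated arrays, and the one after took 7.51% and parted the background sets.

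The targeted genes were read before any other as a check of the labels. Ulk1 was at least 3.44-fold lower in untreated DKO than in untreated WT cells (log2 difference -2.11 ± 0.12 SE, n = 3 per group, limma adjusted p = 8.7e-09), and Ulk2 at least 2.78-fold lower (-2.04 ± 0.14, limma adjusted p = 8.6e-08). After IFNβ the lower bounds were 2.94-fold for Ulk1 and 1.83-fold for Ulk2. The other probe of Ulk2 gave -1.32 untreated and -0.82 after IFNβ (both called). The array holds 2 probes for each gene, and all of them were detected on 6 of 6 WT arrays and 0 of 6 DKO arrays. IFNβ lowered Ulk2 in WT cells, where it fell by 0.51 ± 0.14 on the log2 scale (adjusted p = 0.020), a call lost without untreated replicate 1 (adjusted p = 0.064), without untreated replicate 2 (0.084) or without treated replicate 3 of the WT arrays (0.086). The change of Ulk1 in WT cells was -0.13 (adjusted p = 0.49).

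**Figure D1:**
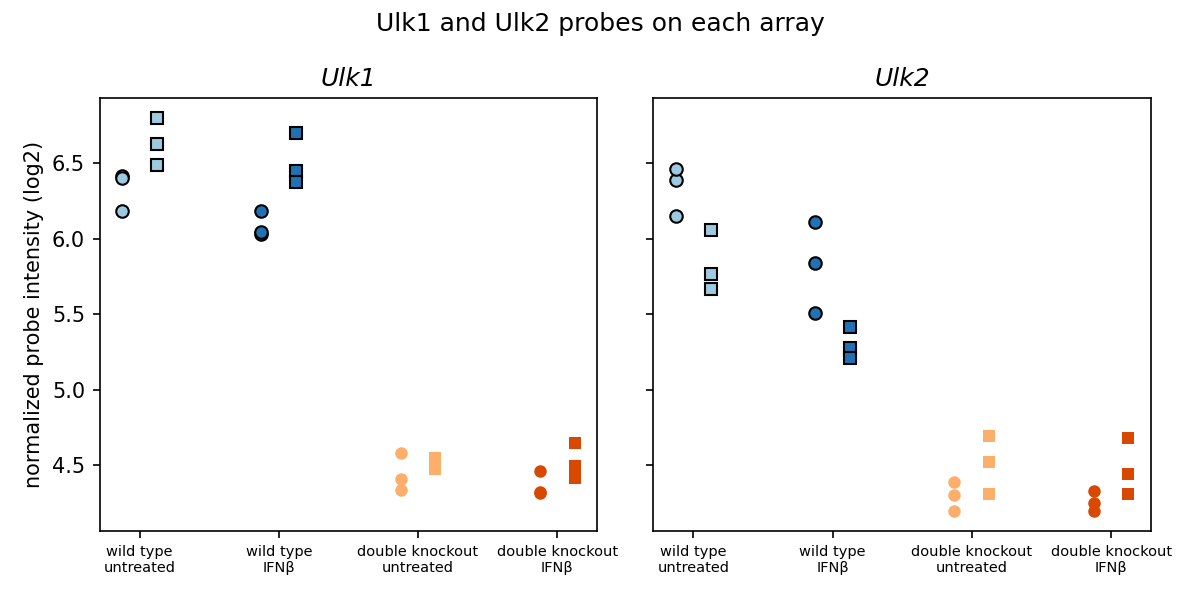
Log2 signal of the probes for Ulk1 and Ulk2 on each of the 12 arrays by group, with circles and squares for the 2 probes of a gene and a black outline where the probe was detected. Every WT array lies above every DKO array, and no DKO array has a detected signal.

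IFNβ strongly raised antiviral and antigen-presentation genes in WT cells. Rsad2, which encodes the antiviral enzyme viperin, rose 109.6-fold (log2 change 6.78 ± 0.24 SE, n = 3 per group, limma adjusted p = 1.1e-10, detected on 2 of 3 untreated arrays). Ifit3, an interferon-induced RNA-response gene, rose 106.8-fold (6.74 ± 0.27), the T cell chemokine Cxcl10 rose 91.1-fold (6.51 ± 0.20) and the guanylate-binding protein Gbp2 rose 66.0-fold (6.04 ± 0.26). Other probes gave 5.69 for Cxcl10, and 4.32 and 3.28 for Gbp2, whose fold therefore depends on the probe. Cmpk2 rose by 5.80 ± 0.17 on the log2 scale, the immunity-related GTPase Ifi47 by 5.34 ± 0.18, Phf11d by 5.28 ± 0.22 and Oasl1 by 5.20 ± 0.17. Cmpk2 and Oasl1 were detected on 1 of 3 untreated WT arrays, so these rises are less certain, and the other probes of Oasl1 gave 2.44 and 4.58. Among genes not detected on any untreated WT array, the oligoadenylate synthetase Oas2 rose at least 16.7-fold, the peptide transporter subunit Tap1 at least 14.3-fold, the chemokine Cxcl9 at least 12.0-fold and the class I transactivator Nlrc5 at least 11.2-fold. Falls were smaller. The transcription factors Sox11 and Foxq1 fell by 1.65 ± 0.13 and by 1.51 ± 0.14 on the log2 scale, the lysosomal proton pump subunit Atp6v0a1 fell by 1.32 ± 0.16 and the RNA-editing enzyme Adarb1 fell by 1.22 ± 0.13. The other probe of Sox11 gave -0.32, which did not pass the test (adjusted p = 0.18). The oxygen-sensing hydroxylase Egln3 was at least 1.73-fold lower.

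Of 8898 tested genes, 1668 changed in WT cells, 719 higher and 949 lower, and 300 changed at least 2-fold, 284 higher and 16 lower, or 190 without background correction and 188 with the authors' values. With the background set as a block the count was 2611 (950 higher, 1661 lower), and with same-numbered arrays of a genotype as a block it was 2804 (1016 higher, 1788 lower). Within the lower and the higher background set alone it was 1213 and 748. The share of rises was 43.1%, and 58.0% after cyclic loess scaling (811 higher, 587 lower), so the balance of small rises and falls turns with the scaling while the 2-fold changes are mostly rises.

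Interferon-stimulated genes moved together in WT cells. Of 65 tested antiviral genes, 63 rose and 0 fell (64 and 0 adjusted over the list alone), with a median log2 change of 2.76, or 2.60 with undetected genes at their bound (camera adjusted p = 1.6e-95). Of 25 genes of MHC class I presentation and the immunoproteasome, 22 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 5.0e-38), among them the proteasome subunit Psmb9 at 4.40 ± 0.19 and Cd274, which encodes the checkpoint ligand PD-L1, at 3.80 ± 0.11. All 13 tested interferon-inducible GTPases rose (13 adjusted over the list alone; camera adjusted p = 8.8e-27), including Igtp at 4.92 ± 0.27 and Gbp3 at 4.85 ± 0.27. Of 20 chemokines and cytokines, 13 rose and 0 fell (15 and 1 adjusted over the list alone; camera adjusted p = 4.3e-12), including Ccl7 at 2.60 ± 0.17 and Il15 at 2.40 ± 0.17, whose other probes gave 1.06 and 2.42. Of 28 components of the interferon pathway, 11 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 2.9e-06). They included Usp18, the deconjugase that dampens receptor signalling, at 4.37 ± 0.22, the transcription factor Irf7 at 4.24 ± 0.19, Irf5 at least 7.72-fold higher and Stat2 at least 6.05-fold higher. The lists share members such as Usp18. With an estimated correlation the camera adjusted p was 0.0062 for antiviral genes, 0.018 for MHC class I and 3.3e-04 for GTPases. It was 0.0062 for chemokines and cytokines and 0.047 for the interferon pathway.

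The ER stress and ATF4 list rose as well in WT cells. Of 30 ER stress and ATF4 target genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 7.9e-05), led by the transcription factor Ddit3 at 1.61 ± 0.16, the glutathione-degrading enzyme Chac1 at 1.04 ± 0.13 and Nupr1 at 0.64 ± 0.12. Of 17 fibroblast markers, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0047, and adjusted p = 0.052 with an estimated correlation; 0.060 in the higher background set alone), including Ly6c1 at least 2.87-fold, Twist1 at 0.84 ± 0.12 and Prrx1 at 0.78 ± 0.14, for which 3 other probes passed and 1 did not (0.33). Of 30 list calls over all 5 comparisons, 19 held with an estimated correlation, and the 11 that did not carry that p-value where they are given. Of 31 p38 MAPK and AP-1 genes, 8 rose and 2 fell (8 and 4 adjusted over the list alone), which did not pass as a list (camera adjusted p = 0.24); the mRNA-decay factor Zfp36 rose by 1.55 ± 0.17 and Fosb by 1.40 ± 0.31.

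In DKO cells IFNβ raised many of the same genes. Cxcl10 rose 22.9-fold (log2 change 4.52 ± 0.20 SE, n = 3 per group, limma adjusted p = 1.9e-09), Gbp2 rose 22.5-fold (4.49 ± 0.26), Phf11d rose by 4.26 ± 0.22 (3.67 with its other probe), Rsad2 rose 17.8-fold (4.15 ± 0.24), Ifit3 rose by 4.09 ± 0.27 on the log2 scale and Ifi47 by 3.61 ± 0.18. The other probes of Gbp2 gave 4.16 and 3.34, near their WT values, so the lower fold of Gbp2 in DKO cells is seen with 1 probe only. The DNA-sensor family member Ifi205 rose by 4.22 ± 0.13, from detection on 1 of 3 untreated arrays, and its other probes gave 1.43 and 2.37. Hap1, a huntingtin-associated transport protein, rose by 3.96 ± 0.15, while its other probe gave 0.51. Phf11a rose at least 11.4-fold, the pore-forming Mpeg1 at least 6.63-fold, Irf5 at least 6.47-fold and the antiviral GTPase Mx1 at least 3.91-fold. The growth factor Pdgfb fell by 1.31 ± 0.15, Sox11 fell by 1.20 ± 0.13 (its other probe gave -0.24, not called), Atp6v0a1 fell by 1.16 ± 0.16 and the desaturase Scd2 fell by 1.11 ± 0.22.

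In DKO cells 1015 genes changed, 556 higher and 459 lower, and 231 changed at least 2-fold, 226 higher and 5 lower, or 135 without background correction, 136 with the authors' values and 145 among genes detected on all 12 arrays. The count was 1718 with the background set as a block (746 higher, 972 lower), 1923 with same-numbered arrays as a block (810 higher, 1113 lower), and 325 and 1066 within the lower and the higher background set, which hold 1 and 2 arrays of each DKO group. The share of rises was 54.8%, against 69.8% after median scaling and 66.3% after cyclic loess, while both blocks turn the balance to falls, so it is not settled.

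The interferon lists moved in DKO cells too. Of the 65 antiviral genes 62 rose and 1 fell (64 and 1 adjusted over the list alone), with a median of 2.12, or 2.11 with undetected genes at their bound (camera adjusted p = 5.5e-96). The 1 that fell was Ifi27, by 0.50, named after its values were seen. Of the MHC class I genes 21 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 2.0e-36), with Psmb9 at 3.57 ± 0.19 and Tap2 at 3.48 ± 0.15. All 13 GTPases rose (13 adjusted over the list alone; camera adjusted p = 3.3e-26), with Gbp3 at 3.19 ± 0.27. Of the chemokines and cytokines 11 rose and 0 fell (12 and 2 adjusted over the list alone; camera adjusted p = 1.9e-08), with Il18 at 1.55 ± 0.17. Of the interferon pathway genes 11 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 4.5e-07), with Irf7 at 2.93 ± 0.19 and Stat2 at 2.34 ± 0.12. Of the ER stress genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.4e-04). Of the p38 MAPK and AP-1 genes 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 6.4e-04, and adjusted p = 0.34 with an estimated correlation), led by the immediate-early genes Fosb at 2.82 ± 0.31, Fos at 2.11 ± 0.37 and Atf3 at 1.45 ± 0.18.

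The responses overlapped. Of 719 rises in WT and 556 in DKO cells, 448 were shared, where independent lists would share 44.9, and of 949 and 459 falls 261 were shared, against 49.0. Of the 284 genes that rose at least 2-fold in WT cells, 257 were called in DKO cells and 248 had a smaller change there. Choosing genes by their WT rise favours this. Of 226 genes that rose at least 2-fold in DKO cells, 70 had a smaller change in WT cells. A difference between genotypes passed its own test for 63 of the 284, of which 60 were smaller in DKO. Across the 1972 genes called in either genotype the slope of the DKO on the WT change was 0.70. Selection on WT alone gave 0.69 and on DKO alone 0.76, and the antiviral list 0.52. Genes are not independent replicates of such a slope.

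**Figure D2:**
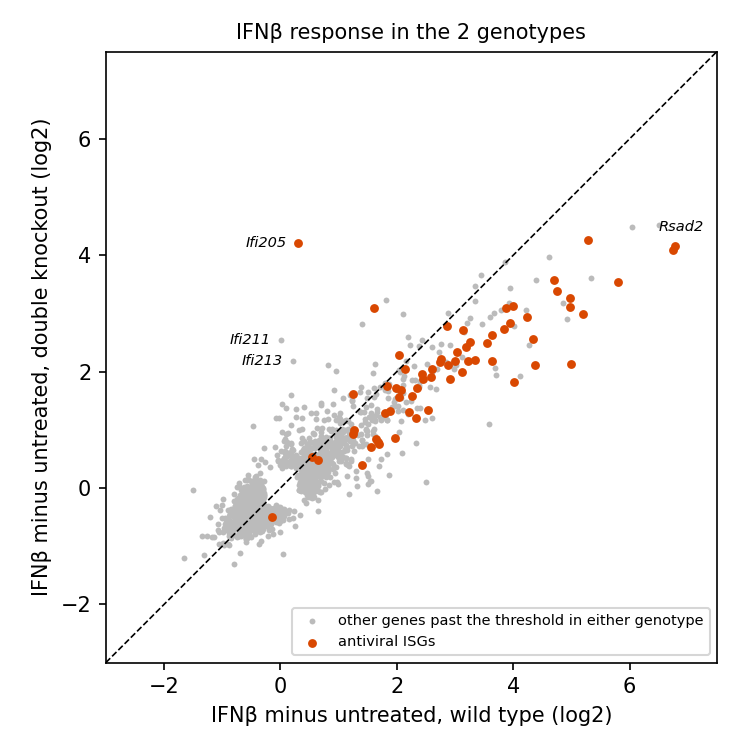
Log2 change with IFNβ in DKO cells against that in WT cells for genes past the threshold in either genotype, with antiviral genes in orange and a dashed line at equality. Many antiviral genes lie below the line, and Ifi205, Ifi211 and Ifi213 lie above it.

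Whether the response differs between the genotypes is the question of the interaction, the change in DKO minus the change in WT cells. The cultures also differed in sex, as given below, so a difference cannot be assigned to Ulk1 and Ulk2 alone. A set of strongly induced antiviral genes rose less in DKO cells. The interaction was -2.87 ± 0.38 log2 (SE, n = 3 per group, limma adjusted p = 0.0013) for the oligoadenylate synthetase-like gene Oasl2, -2.65 ± 0.38 for Ifit3 (adjusted p = 0.0021), -2.63 ± 0.34 for Rsad2 (0.0011), -2.26 ± 0.31 for Usp18, -2.25 ± 0.24 for Cmpk2 and -2.19 ± 0.31 for the ubiquitin-like modifier Isg15. Gch1, the entry enzyme of tetrahydrobiopterin synthesis, had -2.38 ± 0.20 (adjusted p = 3.9e-05). It averaged 7.86 untreated and 10.35 treated in WT cells, and 6.79 and 6.90 in DKO cells. Oasl1 had -2.21 ± 0.24. Other probes gave smaller values for some of these, with -1.84 for Ifit3 (called), -0.94 for Gch1 (adjusted p = 0.10), -0.06 and -1.51 for Oasl1 and -0.53 and -1.23 for Oasl2. The larger value passed the test for Oasl1 and for Oasl2. Cmpk2 and Oasl1 were detected on 1 of 3 untreated WT arrays. Few genes rose more in DKO cells. They included the immediate-early transcription factor Egr2 at 1.54 ± 0.26, the vascular transcription factor Klf2 at 1.28 ± 0.20, Bhlhb9 at 0.96 ± 0.16, and 2 members of the Ifi200 family of DNA sensors, Ifi205 at 3.92 ± 0.19 and Ifi213 at 1.96 ± 0.20. Ifi205 was detected on 0 of 6 WT arrays, so its WT change was not measured, and its other probes gave 0.72 (adjusted p = 0.33) and 2.35 (called).

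The interaction passed for 93 genes, 27 higher and 66 lower, and for 66 with a difference of at least 2-fold, 14 higher and 52 lower. The 66 became 32 without background correction or with the authors' values and 41 with an offset of 50, and among genes detected on all 12 arrays the counts were 43 and 31. The count was 201 (64 higher, 137 lower) with the background set as a block, 254 (76 higher, 178 lower) with same-numbered arrays of a genotype as a block, and 24 and 39 within the lower and the higher background set. At an unadjusted p under 0.05 it was 817. Of the 93 genes, 64 had a smaller rise in DKO, of which 38 were higher and 11 lower in untreated DKO than WT cells and 15 were not called. The same 64 were lower in DKO after IFNβ in 32 cases, higher in 8 and not called in 24. A larger rise in DKO was found for 22 genes, 20 of them higher in DKO after IFNβ.

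Of the 65 antiviral genes, 26 rose less in DKO and 2 rose more, Ifi205 and Sp100 (1.49, named after its values were seen). Adjusted over the list alone these were 51 and 3, and with the background set as a block 39 and 2. The median interaction was -0.81 (camera adjusted p = 6.4e-47, and 0.026 with an estimated correlation). The mean over the 65 genes was 6.55 ± 0.22 log2 (SD, n = 3) in untreated and 9.49 ± 0.04 in treated WT cells, and 7.52 ± 0.10 and 9.63 ± 0.03 in DKO cells. It rose by 2.94 ± 0.10 (SE) in WT and by 2.11 ± 0.10 in DKO cells, a difference of -0.83 ± 0.14, or -0.54 without background correction. For the 6 treated arrays' rises over the untreated mean of their own genotype, the 2-sided exact permutation p was 0.1, the smallest that 20 assignments of these rises allow. The spread of the untreated arrays does not enter it. Inside the lower and the higher background set the difference was -0.90 and -0.88. These values rest on lone DKO arrays in the lower set and lone WT arrays in the higher set. Untreated DKO arrays lay above WT arrays by 0.97, 3 of 3 above each WT array, and treated DKO arrays above treated WT arrays by 0.13. WT untreated replicate 1 stood at 6.81, against 6.39 and 6.46 for the other two.

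The untreated arrays enter both the interaction and the untreated comparison, which ties the results together. Genes simulated with no effect show the size of this tie. They vary independently of each other, while antiviral genes move together, so the simulated values are no test of the list. Of 61 antiviral genes with a negative interaction 57 (93.4%) were higher untreated in DKO cells, where simulated genes with no effect gave 74.5%, and 35 (57.4%) were lower after IFNβ, where they gave 74.3%. All 26 antiviral genes with a called smaller rise were called higher in untreated DKO cells, and 1 was called lower after IFNβ. Over the members, the covariance of interaction and untreated difference was -0.48, where simulated genes gave -0.02, and that of interaction and difference after IFNβ was 0.44, where they gave 0.02. As the interaction is the difference of these 2, the covariances do not tell which of them carries it. The list means do, on the log2 scale. DKO lay above WT by 0.97 ± 0.10 (SE) untreated and by 0.13 ± 0.10 after IFNβ. The smaller rise of the list mean therefore lies in the higher untreated level, not in a lower level after IFNβ. Over all tested genes, 40 of 66 with a negative interaction were higher untreated and 32 lower after IFNβ. Shared arrays tie these lists, so their overlap is not set against that of independent lists.

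**Figure D3:**
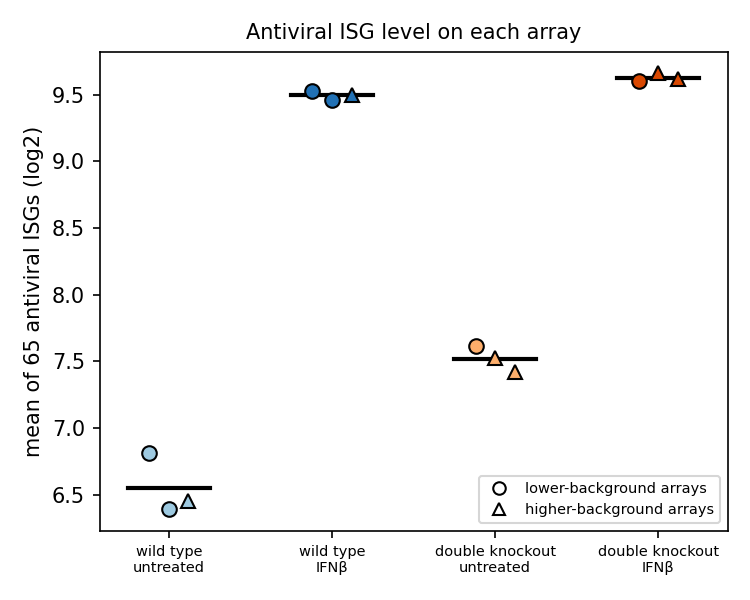
Mean log2 signal of the 65 tested antiviral genes on each array by group, with bars at the group means, circles for arrays of the lower and triangles for arrays of the higher background set. Untreated WT arrays lie between 6.39 and 6.81 and untreated DKO arrays between 7.42 and 7.61, while treated arrays of both genotypes lie between 9.46 and 9.66.

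Other interferon lists also rose less in DKO cells. Of the 13 GTPases 4 had a smaller and 0 a larger rise (11 and 1 adjusted over the list alone; median -1.12, camera adjusted p = 1.8e-15), including Irgm2 at -1.82 ± 0.24 and Ifi47 at -1.73 ± 0.25. Of the 20 chemokines and cytokines 4 had a smaller and 0 a larger rise (7 and 2 adjusted over the list alone; median -0.40, camera adjusted p = 3.1e-07), including Cxcl9 at -2.19 ± 0.26 and Cxcl10 at -1.99 ± 0.28, whose other probe gave -1.26 (adjusted p = 0.45). Cxcl9 was not detected on any untreated array of either genotype, so its value rests on untreated signals that were not measured. Of the 25 MHC class I genes 2 had a smaller rise (16 adjusted over the list alone; median -0.52, camera adjusted p = 1.8e-14, and adjusted p = 0.11 with an estimated correlation), including Tap1 at -1.23 ± 0.20, undetected on untreated WT arrays. The interferon pathway list did not pass, with 0 larger and 2 smaller (1 and 4 adjusted over the list alone; camera adjusted p = 0.10). The p38 MAPK and AP-1 list was shifted upward with 1 member called, Egr2 (1 adjusted over the list alone; median 0.10, camera adjusted p = 0.036, and adjusted p = 0.61 with an estimated correlation). That list call was lost without WT untreated replicate 1 (0.195), WT treated replicate 1 (0.172), DKO untreated replicate 2 (0.061) or 3 (0.090) or DKO treated replicate 1 (0.085), and among genes detected on all 12 arrays (0.067) or in the higher background set (0.325). The 19 NF-kB targets did not pass as a list, with 1 member higher and 1 lower in the interaction (camera adjusted p = 0.61). The lower one was the inhibitor Nfkbia at -1.05 ± 0.18, and its other probe gave -0.66 (not called).

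Untreated DKO and WT cells differed widely, which shows what the genotypes brought to the experiment before IFNβ. Csrp1, a LIM-domain protein of the actin cytoskeleton, was 41.3-fold higher in DKO cells (log2 difference 5.37 ± 0.15 SE, n = 3 per group, limma adjusted p = 7.6e-12). The basement membrane collagens Col4a1 and Col4a2 were 22.6-fold (4.50 ± 0.12) and 22.3-fold (4.48 ± 0.13) higher, the interferon-inducible Ifi27l2a 18.1-fold (4.17 ± 0.32) and the imprinted gene Ndn by 3.08 ± 0.11. The transcription factor Gata3 was at least 8.09-fold and the keratin Krt19 at least 7.90-fold higher. On the other side, the LIM protein Pdlim4 was lower, with a difference of -5.20 ± 0.17 (its other probe gave -0.55, also called), and so were the secreted signal Wnt10a at -5.19 ± 0.13, the microtubule regulator Stmn2 at -4.92 ± 0.14, the axial patterning gene Hoxc9 at -4.86 ± 0.13 and the xenobiotic oxidase Cyp1b1 at -4.12 ± 0.17. The carbonic anhydrase Car12 was at least 15.8-fold lower (-1.73 log2 with its other probe), and the receptor Pdgfra was also lower and not detected on any untreated DKO array. The cultures also differed in genes of sex. Xist, the RNA that coats an inactive X chromosome, was detected by 4 probes on all 6 DKO and 0 of 6 WT arrays, and the Y-linked gene Eif2s3y by 1 of its 2 probes on 6 WT and 0 DKO arrays.

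Of the tested genes 3013 differed, 1411 higher and 1602 lower in DKO, and 568 at least 2-fold, 330 higher and 238 lower. The 568 became 211 without background correction, 210 with the authors' values, 324 with an offset of 50 and 334 among genes detected on all 12 arrays. The count was 3832 with the background set as a block, and 1582 and 2351 within the lower and the higher set. Of the antiviral genes 46 were higher and 0 lower in untreated DKO cells (47 and 0 adjusted over the list alone; median 0.78, or 0.75 with bounds; camera adjusted p = 2.1e-18, and adjusted p = 0.16 with an estimated correlation). They included Oasl1 at 2.71 ± 0.17, Oasl2 at 2.58 ± 0.27 and the oligoadenylate synthetase Oas1g at 2.36 ± 0.16. The less bright probes of Oasl2 gave 1.03 (called) and 0.12 (not called), those of Oasl1 0.66 and 2.12 (both called), and those of Oas1g 1.38 (called), 0.07 and 0.08 (not called). Of the GTPases 8 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 5.0e-04), including Gvin1 at 2.19 ± 0.16 (0.41 with its other probe) and Irgm2 at 1.61 ± 0.17. Of the ER stress genes 10 were higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.088 with an estimated correlation), including Ddit3 at 1.34 ± 0.16 and Chac1 at 1.27 ± 0.13. Of 12 smooth muscle markers 8 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.0012), including the myosin light chain Myl9 at 1.26 ± 0.10 and the actin Actg2 at 1.00 ± 0.10. Of 42 matrix genes 19 were higher and 9 lower (20 and 10 adjusted over the list alone; camera adjusted p = 0.0081, and adjusted p = 0.57 with an estimated correlation), with Col18a1 at 2.02 ± 0.14 (1.06 with its other probe). Of 5 epithelial markers 3 were higher and 0 lower (3 and 0 adjusted over the list alone; median 0.77, or 0.12 with bounds; camera adjusted p = 0.017, and adjusted p = 0.11 with an estimated correlation). The epithelial list call was lost with no filter on dim probes (adjusted p = 0.078).

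The autophagy list, which leaves out Ulk1 and Ulk2, did not pass as a list in any comparison (camera adjusted p = 0.83 untreated). Of its 37 tested genes 4 were higher and 7 lower in untreated DKO cells. As 3013 of all 8898 tested genes differed there, this is no larger a share than among all genes. The conjugating enzyme Atg3 had -2.07 ± 0.19, the nucleation subunit Becn1 -0.78 ± 0.11 and Map1lc3a, which encodes a lipidated autophagosome protein, 0.80 ± 0.17. The other probe of Becn1 gave -0.07 and that of Map1lc3a 0.06, and neither passed (adjusted p = 0.84 and 0.80). IFNβ lowered 4 of the 37 in WT and 1 in DKO cells (2 in WT adjusted over the list alone). In WT cells the phosphoinositide-binding Wipi2 fell by 0.71 ± 0.14 and Atg2b fell by 0.47 ± 0.11, and in DKO cells Wipi1 fell by 0.60 ± 0.14, a call lost without DKO untreated replicate 2 (adjusted p = 0.055). Other probes gave -0.11 for Atg2b (adjusted p = 0.59), -0.46 (called) and -0.40 (adjusted p = 0.075) for Wipi2, and -0.44 (not called) and -0.42 (called) for Wipi1. In the interaction the smallest p-values of the list belonged to the protease Atg4c at -0.67 (limma adjusted p = 0.30) and Gabarap at -0.52 (0.38), which did not pass.

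After IFNβ the genotypes differed in much the same measure. Csrp1 was 5.31 ± 0.15 log2 higher in DKO cells (n = 3 per group, limma adjusted p = 6.8e-12), Col4a2 4.33 ± 0.13 and the myosin light chain kinase Mylk 3.38 ± 0.26 (2.01 and 2.08 with its other probes). Ifi205 was at least 16.4-fold (0.81 and 2.49 log2 with its other probes), the cytoskeletal protein Shroom2 at least 12.4-fold and Snurf at least 7.89-fold higher (1.88 log2 with its other probe). AA467197 differed by -6.34 ± 0.16, Stmn2 by -5.03 ± 0.14 and the transcription factor Tfap2a by -4.11 ± 0.13 (-3.18 with its other probe). Pdlim4 was at least 31.0-fold (-0.42 log2 with its other probe), Wnt10a at least 29.1-fold and Pdgfra at least 16.2-fold lower. Secreted mediators were lower in treated DKO cells. Of the 20 chemokines and cytokines 13 were lower and 1 higher (14 and 1 adjusted over the list alone; median -0.74, or -0.71 with bounds; camera adjusted p = 4.7e-06, and 0.026 with an estimated correlation). The interleukin-1 antagonist Il1rn was at least 11.9-fold lower, Cxcl9 had -2.26 ± 0.19, the monocyte chemokine Ccl2 -1.94 ± 0.22 and Il15 -1.66 ± 0.17. The antiviral list did not differ as a list after IFNβ (camera adjusted p = 0.66). It held 13 genes higher and 9 lower (13 and 9 adjusted over the list alone), and its median of -0.03 differed in sign from its mean of 0.13 and from the test's upward direction. Ifi27l2a had 3.06 ± 0.32 and the nuclear body protein Sp100 2.47 ± 0.12.

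After IFNβ 2831 genes differed, 1362 higher and 1469 lower in DKO, and 571 at least 2-fold, 309 higher and 262 lower. The 571 became 211 without background correction or with the authors' values, 317 with an offset of 50 and 304 among genes detected on all 12 arrays. The count was 3597 with the background set as a block, and 1602 and 1907 within the lower and the higher set. Of the 25 MHC class I genes 0 were higher and 9 lower (0 and 9 adjusted over the list alone; median -0.34, camera adjusted p = 0.011, and adjusted p = 0.70 with an estimated correlation), including the class I genes H2-Q6 at -1.93 ± 0.19 (-1.10 with its other probe) and H2-T10 at -0.67 ± 0.17. Of the other probes of H2-T10, 1 gave the opposite call at 3.88 and 1 the same call at -0.96. Smooth muscle markers stayed higher, 6 of 12 with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0015), with Myl9 at 1.18 ± 0.10. Of the matrix genes 18 were higher and 11 lower (19 and 12 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.69 with an estimated correlation). The matrix call was lost without WT treated replicate 2 (0.072) or DKO treated replicate 1 (0.066). Of the 5 epithelial markers 3 were higher (3 adjusted over the list alone; median 0.48, or 0 with bounds; camera adjusted p = 0.039, and adjusted p = 0.16 with an estimated correlation). That call was lost without WT treated replicate 1 (0.064) or DKO treated replicate 2 (0.054) with the background set (0.066) or the replicate number (0.060) as a block, without background correction (0.077), with the authors' values (0.077), with an offset of 50 (0.072) and after cyclic loess (0.052), so it is weak. The matrix call was also lost after median scaling (0.072), with a looser detection filter (0.058), with the replicate number as a block (0.085) and in the higher background set (0.090), and the MHC class I call among genes detected on all 12 arrays (0.054).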

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

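Of the tests in this part, those on the background sets, the array ceiling, different embryos, the Ifi200 gene cluster, a strain variant and the splits with effects taken out were chosen after the result was seen.

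The response to IFNβ differed between the genotypes by a test of the difference itself for 93 genes, among them antiviral genes whose rise was smaller in DKO cells. The interaction was -2.87 for Oasl2, -2.65 for Ifit3, -2.63 for Rsad2, -2.26 for Usp18, -2.25 for Cmpk2, -2.21 for Oasl1 and -2.19 for Isg15, and -2.38 for Gch1. As lists, the same test gave medians of -0.81 for the antiviral genes, -1.12 for the interferon-inducible GTPases, -0.52 for MHC class I and the immunoproteasome (adjusted p = 0.11 with an estimated correlation) and -0.40 for the chemokines and cytokines. The p38 MAPK and AP-1 list had a median of 0.10 (adjusted p = 0.61 with an estimated correlation).

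The smaller rise of the antiviral list came with a higher untreated level in DKO cells (adjusted p = 0.16 with an estimated correlation), and technical causes were set against a difference between genotypes. The background sets are argued against as the cause, since the difference of induction was -0.88 in the set where it lay nearer 0. Each set holds lone arrays of 1 genotype, which limits this comparison. A constant shift between the sets cannot give the difference, as each genotype has the same mix of sets treated and untreated. A set effect that changes with treatment rests on the limited comparison. A ceiling of the array signal is argued against as the whole cause. The 35 members under a log2 level of 10 in treated WT cells had a median interaction of -0.69 (mean -0.50). The 30 brighter members had a median of -1.01 (mean -1.22), so a part is not excluded. RNA of treated cells carried into untreated DKO samples stays open: other genes raised at least 4-fold in DKO cells implied a median share of 2.55% treated RNA (95% bootstrap interval 1.01 to 4.06, 51 genes), against 6.75% for 36 antiviral members, and a bound of 50% set beforehand was not met. A raised resting interferon tone in DKO cells may account for the same values and was not tested apart from that. Sex and culture differed along with the genotype and cannot be told apart from it in this smaller rise.

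Untreated DKO and WT cells differed in 3013 genes, and the cultures differed in more than Ulk1 and Ulk2. Xist was detected on DKO arrays only and Y-linked genes on WT arrays only, so the cultures differed in sex. Linked DNA stays open: genes near Ulk1 and Ulk2 made up 5.81% of the called genes, a share that could not pass 13.3% and so decides nothing, and 43.8% of them were called against 33.4% elsewhere (Fisher's exact p = 2.9e-05, with genes not independent). How many of the 3013 genes the difference in sex accounts for stays open as well. Genes on the X or Y chromosome made up 3.79% of the called genes, where 9.10% was the most possible. Of the genes on X or Y, 41.6% were called against 33.6% elsewhere (Fisher's exact p = 0.0064). Other embryo differences, or regional identity, cannot be told apart from the loss of Ulk1 and Ulk2, as each genotype may be 1 culture. Of 16 Hox genes 13 differed, in both directions. The list did not pass camera (adjusted p = 0.29), which asks for a shift in 1 direction. Loss of the kinases themselves stays open on the same grounds.

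Ifi213 rose more in DKO cells, with an interaction of 1.96, and Ifi205 with 3.92, and so did Ifi211 (2.55) and Ifi207 (1.41), these last named after their values were seen. Ifi205 and Ifi211 were detected on 0 of 6 WT arrays and Ifi207 on 0 of 3 untreated WT arrays, so their WT changes were not measured. A single change acting on the whole Ifi200 gene cluster is argued against by 2 tested members with an interaction under 0.5, Ifi204 at -0.10 ± 0.17 (undetected on untreated WT arrays) and Ifi202b at -0.66 ± 0.26, also named after their values were seen. A strain variant in these genes or under their probes cannot be told apart from a regulatory difference, as no sequences were used here; the median WT change of the members with a larger rise, 0.25, includes the unmeasured ones. A difference that follows from the loss of Ulk1 and Ulk2 may give the same values, and was not tested.

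Egr2 had an interaction of 1.54, Klf2 of 1.28 and Bhlhb9 of 0.96. Lesser positive interactions were found for Taf9b at 0.82, Stc2 at 0.82, Pla2g4b at 0.80 and Fastkd3 at 0.77. That of Pla2g4b comes mostly from WT cells, with -0.57 there and 0.23 (not called) in DKO cells, and Fastkd3 (-0.38 and 0.39) and Taf9b (-0.33, not called, and 0.49) moved both ways. Each of these 4 calls was lost on leaving out any of most single arrays. The highest adjusted p was 0.091 for Taf9b without DKO untreated replicate 2, 0.083 for Stc2 without WT treated replicate 1, 0.081 for Pla2g4b without DKO untreated replicate 2 and 0.115 for Fastkd3 without DKO treated replicate 2. Of 2119 detected probes annotated to no gene or to several, which enter no comparison above, 251 changed with IFNβ in WT cells, 117 higher, 49 of them at least 2-fold, and 134 lower, and 154 changed in DKO cells.

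Other splits of the arrays were counted. For the interaction, 4 of 100 drawn splits gave at least as many genes as the real 93, the real one included, and the highest others gave 1554, 732 and 152. Exchanged arrays carry the genotype difference with them, so this count alone does not decide whether chance can be excluded. With the genotype effect of an additive model taken out, again 4 of 100 splits gave as many as 93. The highest other split then gave 1810 genes and parts the background sets fully within each treatment, which is a structure of the samples. With the set also taken out, 1 of 100 splits, the real one, gave as many as the real 305, and the highest other gave 0. With a block of the set the test calls 201 genes. Each kind of split gave a share under 0.05, the raw one and the one without the genotype effect narrowly. The limit of 0.05 on the raw count was set beforehand, but that count carries the genotype difference. The last 2 kinds of split were chosen after the raw count was seen, and the 305 takes no account of the effects fitted beforehand. Chance is therefore not excluded, and splits of these arrays cannot speak to chance differences between cultures. For the other contrasts, each with 3 arrays against 3, only 10 splits exist, too few for a share under 0.05. The real split, fitted on the 6 arrays of the contrast, gave 1328 genes for IFNβ in WT, 835 for IFNβ in DKO, 2842 for the genotypes untreated and 2520 after IFNβ. In each of these 1 split, the real one, gave as many, and the highest other gave 0.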

How the results depend on the processing

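The block of the background sets, each set alone, the replicate block within genotype and the subsets of the antiviral list were chosen after seeing the data. Over 38 settings, 442 gene results kept their direction and side of the threshold in 11958 comparisons, lost the call in 809 and reversed in 1; 30 list results kept it in 787 and lost it in 30. Ulk1 and Ulk2 stayed lower in DKO in every setting run. The reversal was H2-T10 after IFNβ, 0.75 with the mean of a gene's probes against -0.67, as 1 of its other probes has the opposite sign. Without background correction the 2-fold counts were 190 (IFNβ in WT), 135 (IFNβ in DKO), 32 (interaction), 211 (untreated) and 211 (after IFNβ) and the antiviral difference was -0.54; with the authors' values they were 188, 136, 32, 210 and 211, and -0.54. Background left in the signal compresses folds. An offset of 50 gave 2-fold counts of 41 (interaction), 324 (untreated) and 317 (after IFNβ) and an antiviral difference of -0.64, by the same construction. Among genes detected on all 12 arrays, where fewer are tested, the interaction count was 43 (31 at least 2-fold), the 2-fold counts 145 (IFNβ in DKO), 334 (untreated) and 304 (after IFNβ), and the antiviral difference -0.99. At an adjusted p under 0.01 the counts were 939, 576, 59, 1958 and 1816, which a stricter threshold must lower. The replicate block over all arrays gave 153 interaction genes; the block of the background sets gave 2611 (WT), 1718 (DKO) and 201 (interaction), and the replicate block within genotype 2804, 1923 and 254. Every gene called without a block was also called with these. The fixed replicate block ended the list calls of matrix (adjusted p = 0.085) and epithelial genes (0.060) after IFNβ, that of the background sets the epithelial one (0.066), and the block within genotype added a fibroblast interaction (0.030); the blocks changed no other list call. With the 6 lower-background arrays, fewer samples and lone arrays of a group assumed to vary like the other groups, the counts were 325 (IFNβ in DKO), 24 (interaction, 24 at least 2-fold), 1582 (untreated) and 1602 (after IFNβ); with the 6 higher ones 748 (IFNβ in WT) and 39 (interaction, 39 at least 2-fold). With each array left out the antiviral difference ranged from -0.96 to -0.75, against -0.83; the lowest was without WT untreated replicate 1. Antiviral members not called untreated gave a mean difference of -0.39. The untreated arrays enter both this choice and the interaction, so a smaller value is built in. Members under log2 10 gave a mean of -0.50 and a median of -0.69. The slope on the antiviral list was 0.52 against 0.70, and the cause of these changes was not tested. Of 30 list calls, 19 passed with an estimated correlation and 62 tests passed with fry, which asks another question. A slide block was not run, because the files name no slides. Signal over background limits the folds of dim genes, which are given as bounds.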

Other observations

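No test in this part was chosen after its result was seen.

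Single developmental and position genes differed between the cultures, while their lists did not pass camera. That test asks for a shift in 1 direction against other genes, so it can miss lists whose members go both ways. The directional fry test uses no other genes, but also asks for a shift in 1 direction. With it the Hox, imprinted, neural, endothelial and fibroblast lists passed untreated (fry adjusted p 7.6e-07 to 0.031). Others passed too, such as the cell cycle list (fry adjusted p = 8.2e-04) and the NF-kB targets (fry adjusted p = 9.9e-04). Passing it therefore does not set the developmental lists apart. The counts stand beside 3013 of all 8898 tested genes that differed untreated. Of 16 tested Hox genes, which mark axial position in the embryo, 5 were higher and 8 lower in untreated DKO cells (5 and 8 adjusted over the list alone; camera adjusted p = 0.29 as a list), with Hoxd10 at least 6.26-fold higher and Hoxc10 at least 6.61-fold lower (-2.27 log2 with its other probe). After IFNβ 4 were higher and 6 lower (5 and 7 adjusted over the list alone). Of 9 imprinted genes 3 were higher and 2 lower untreated (3 and 2 adjusted over the list alone; camera adjusted p = 0.58), with the cell cycle inhibitor Cdkn1c at 2.82 ± 0.13 and the preadipocyte factor Dlk1 at -1.76 ± 0.14 (limma, n = 3 per group; its other probe gave -0.50, not called), and the same counts held after IFNβ. Of 7 neural markers 2 were higher and 4 lower untreated (2 and 4 adjusted over the list alone; camera adjusted p = 0.27), including the intermediate filament Nes at 1.11 ± 0.10, with 2 and 3 after IFNβ. Of 5 endothelial markers 2 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.64), including the VEGF receptor Flt1 at 1.51 ± 0.13, with 1 and 1 after IFNβ. Of 17 fibroblast markers 6 were higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.94), with Ly6c1 at least 6.84-fold higher and Nt5e at -2.14 ± 0.15, and 6 and 7 after IFNβ.

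Lysosomal and growth genes moved member by member. Of 36 lysosomal genes 7 rose and 1 fell with IFNβ in WT cells (7 and 1 adjusted over the list alone; camera adjusted p = 0.075), including the membrane protein Scarb2 at 1.24 ± 0.11, the cholesterol carrier Npc2 at 1.17 ± 0.14 and the protease Ctsh at 1.13 ± 0.16. In DKO cells 3 rose and 0 fell (4 and 1 adjusted over the list alone). Between untreated genotypes 9 were higher and 5 lower in DKO (9 and 5 adjusted over the list alone), with Gpnmb at 2.78 ± 0.19 (1.27 with its other probe) and the protease Ctsc at least 4.53-fold lower (-1.37 and -0.70 log2 with its other probes), and 6 and 6 after IFNβ. Of 42 cell cycle genes 4 rose and 7 fell in WT and 2 rose and 0 fell in DKO cells, and 6 were higher and 13 lower in untreated DKO (6 and 15 adjusted over the list alone), with the cyclin Ccnd1 at 1.06 ± 0.15 and Ccne2 at -0.80 ± 0.14. Of 20 p53 targets 0 rose and 4 fell in WT cells (0 and 6 adjusted over the list alone), where Zmat3 fell by 0.96 ± 0.11. In DKO cells 0 rose and 1 fell (0 and 5 adjusted over the list alone). Untreated, 6 were higher and 2 lower in DKO (6 and 2 adjusted over the list alone), with the kinase inhibitor Cdkn2b at 1.43 ± 0.12. Of 19 NF-kB targets 5 rose and 2 fell in WT and 5 rose and 1 fell in DKO cells (5 and 2, and 6 and 3, adjusted over the list alone), where the atypical inhibitor Nfkbiz rose by 0.71 ± 0.14 and by 1.02 ± 0.14; 3 were higher and 5 lower in untreated DKO. Of 23 NRF2 targets 3 were higher and 6 lower in untreated DKO (3 and 6 adjusted over the list alone), with the reductase Cbr3 at -2.26 ± 0.12 (-1.24 with its other probe) and the transferase Gstm2 at 1.98 ± 0.19 (2.13 and 1.27 with its other probes); with IFNβ 1 rose and 1 fell in WT cells, where the haem-degrading enzyme Hmox1 rose by 1.21 ± 0.11, and 1 rose and 3 fell in DKO cells.

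The lists of cholesterol synthesis, glycolysis and hypoxia, heat shock, ribosomal protein and oxidative phosphorylation genes did not pass as lists in any comparison. Of 17 cholesterol synthesis genes 4 were higher and 1 lower in untreated DKO (3 and 1 adjusted over the list alone), including Insig1 at 1.46 ± 0.20 (0.56 with each of 2 other probes), and 2 fell in WT cells with IFNβ. Of 19 glycolysis and hypoxia genes 3 were higher and 3 lower, and 1 rose and 4 fell in WT cells. Of 13 heat shock genes 2 rose in each genotype, with the chaperone Hspa1a at 0.95 ± 0.16 in WT cells. Of 33 ribosomal protein genes 1 was higher and 3 lower in untreated DKO, with Rplp0 at -0.92 ± 0.11, and of 46 oxidative phosphorylation genes 4 were higher and 6 lower, with Uqcrc1 at -1.09 ± 0.11. Interferon pathway genes were higher in 7 and lower in 3 of 28 cases in untreated DKO, where the feedback inhibitor Socs3 had -1.03 ± 0.13, and chemokines and cytokines in 2 and 9 of 20 (2 and 9 adjusted over the list alone; camera adjusted p = 0.13), where Il7 had -2.02 ± 0.13 and Ccl5 1.28 ± 0.16. Matrix genes rose in 4 and fell in 1 of 42 cases with IFNβ in WT and rose in 5 in DKO cells, and smooth muscle markers fell in 3 and 2 of 12. Too few genes were tested, under 5, in the lists for skeletal muscle (2), adipocytes (2), cartilage and bone (4), leukocytes (3), pluripotent cells (0) and sex-linked genes (4). Of the last, Kdm5d was detected by 1 of its 2 probes on 5 WT and 0 DKO arrays and Uty by 1 of its 4 probes on 3 WT and 0 DKO arrays.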
